A study of Mus musculus with 8 samples.

How the data were processed

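Expression was measured in CD11b+ cells of NOD and NOD.Idd3 mice on 8 single-channel arrays, with biotin-labelled total RNA on each array. The 4 groups were unstimulated or peptidoglycan-treated (PGN) cells of each strain, with 2 arrays per group. Groups and replicate numbers were taken from the sample labels, and all 8 arrays were used. The labels number the arrays of a group as biological replicates but do not say whether these were separate animals or pools, so p-values measure only the spread between these samples.

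The deposited table holds 1 intensity value per probe set and array, on a linear scale. The labels name RMA, which gives log2 values, so the authors' values had been raised back from the log2 scale. The version, the chip definition and the software are not given in the sources used here. The table's 45101 probe sets had values from 3.97 to 42910 with a median of 44.0. The tests had been planned on log2 values as deposited, and the log2 of each value was taken once the linear scale was seen. Values were otherwise used as deposited, without a further normalization or a filter on dim probe sets.

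Probe sets were paired with genes through the platform annotation. Control probe sets (64) were left out, as were 9160 probe sets with no gene symbol and 932 with several. Of the 34945 probe sets with exactly 1 symbol, 34754 matched the RefSeq gene table of assembly GRCm38.p6, which was used for gene names, chromosomes and neighbour order. Each gene was represented by its probe set with the highest mean over the 8 arrays, which left 18193 genes. Of these, 9012 had more than 1 probe set. Among the genes named for the averaged PGN effect that passed, 37 had other probe sets, and 2 of those 62 probe sets had the opposite sign. Nod2, planned to be named, had no probe set with a single symbol and was not analysed here.

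Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as contrasts of the 4 group means, with 4 residual and 4.69 prior degrees of freedom. The contrasts were the PGN effect in each strain, its average over strains, its difference between strains (NOD.Idd3 minus NOD), and the strain difference unstimulated, with PGN and averaged. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Errors beside log2 changes are limma standard errors. The 2 PGN effects share no arrays, and neither do the strain differences of the 2 conditions. The number of arrays limits the precision.

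Gene lists and cell type marker lists were tested with camera at a preset correlation between genes of 0.01, with the adjustment over the 32 lists that had at least 5 measured genes. Camera was run again with the correlation estimated from the data, without the replicate block, and fry gave a test of change in either direction. Beside each list stand the genes that passed over all genes and the count adjusted over the list alone. The estimate with 4 residual degrees of freedom is imprecise, and differences between replicate numbers left in the residuals can raise it. No list in any contrast passed with this estimate.

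The comparisons, the fixed lists and the rule for naming genes were set before the data were examined, and so were the alternatives and tests not said to have been chosen afterwards. The rule took the 8 largest rises and 8 largest falls of each PGN effect among genes that passed and whose arrays did not overlap between groups. It took the 10 largest changes, or the 5 smallest p-values where fewer than 5 genes passed, for each strain contrast. It also took up to 4 members of each list, a fixed set of cytokines and receptors, and the measured genes of the Idd3 interval and its flanks. Genes named outside this rule are said to have been chosen after their values were seen.

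Replicate numbers could pair the arrays across groups, since the replicate 1 arrays carry a shared date in the labels' array names. The difference between replicates 1 and 2 was correlated across genes between groups, with r from 0.17 to 0.42 over the 6 pairs of groups. The numbers were taken as pairing the arrays in the replicate block, but the main fit has no such term. Differences between replicate numbers therefore stay in the residual spread of the main fit and enter its standard errors. The replicate block, with the number as a term in the fit, was planned as an alternative, and its counts of genes and lists called are given.

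The other alternatives were the array-name suffix RR1 as a term (its meaning is not given in the sources used here), a trend in the variance prior, removal of genes under the 40th percentile of mean value, the mean of all probe sets of a gene, removal of _x_at and _s_at probe sets, a further quantile normalization, array weights, leaving out each array, and fits of the 4 arrays compared. The variance trend does not enter camera, and array weights and fits of 4 arrays were not run for the lists. On simulated data with the same design, the PGN contrast in NOD recovered 11.3% of genes changed by 1 on the log2 scale, 83.3% at 2 and 95.5% at 3. For the strain difference in the PGN response, recovery was 0% at 1, 43.5% at 2 and 94.2% at 3. The simulation changed 62, 72 and 66 genes at these sizes for PGN, with independent noise and no replicate effect. Recovery at a Benjamini-Hochberg threshold depends on how many genes change, so these rates need not hold for the real contrasts.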

Results

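CD11b is an integrin subunit carried by monocytes, macrophages and neutrophils, among other cells. CD11b+ cells were studied from NOD mice, which develop autoimmune diabetes spontaneously, and from the congenic NOD.Idd3 strain, whose chromosome 3 carries another allele at Idd3, a diabetes locus that includes Il2 and Il21. The tissue of origin is not given in the sources used here. Cells were incubated for 4 h at 37 °C in medium alone or with PGN, a bacterial cell wall polymer, at 5 µg/ml. Each of the 4 groups had 2 arrays. The median log2 value per array lay between 5.42 and 5.50, and arrays of the same group were correlated across genes at 0.985 to 0.991. The first principal component held 51.5% of the variance and separated PGN-treated from unstimulated arrays. The second held 17.3% and separated the replicate numbers, and the third held 10.1% and separated the strains.

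The first question was which genes respond to PGN in CD11b+ cells, over both strains together. The cytokine genes Csf3 (log2 change 7.07 ± 0.24, SE, 4 arrays per condition) and Il10 (6.52 ± 0.28) were among the largest rises, after Cyp1b1 (7.79 ± 0.42). Csf3 encodes the neutrophil growth factor G-CSF, and its adjusted p in limma was 9.58e-06. Il12a rose by 3.76 ± 0.53 and Il23a by 4.11 ± 0.52, while Il12b, whose product pairs with both, changed by 0.41 ± 0.23 and did not pass (adjusted p = 0.306). Il6 rose by 2.73 ± 0.38 and Tnf by 1.68 ± 0.20. Il1b stood at 14.26 in unstimulated NOD cells and changed by 0.12 ± 0.16 (adjusted p = 0.706), at a level near the highest value of any gene (15.17), so a compressed rise is not excluded.

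**Figure D1:**
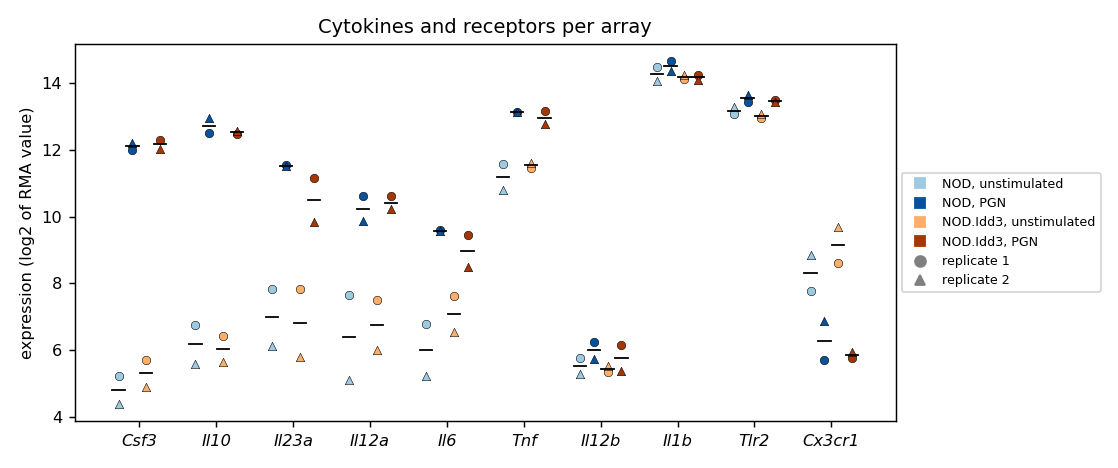
Expression of cytokine and receptor genes (log2 of the RMA value) on each of the 8 arrays, with colour for group, symbol for replicate number and a line for the mean of 2 arrays. Csf3 had a mean of 4.82 in unstimulated and 12.10 in PGN-treated NOD cells, and Il1b had 14.26 and 14.50, near the highest value of any gene (15.17), where a rise would be compressed.

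Of 18193 genes, 2049 passed for the averaged PGN effect, 885 higher and 1164 lower, and 1101 of them changed at least 2-fold. With the replicate block 3082 genes passed, and these included all 2049. The count fell to 1253 without replicate 2 of unstimulated NOD, to 1249 and 1111 without replicates 1 and 2 of unstimulated NOD.Idd3, and to 1299 without replicate 2 of PGN-treated NOD.Idd3. The other large rises were U90926 (6.06), Il1f6 (5.43), Fst (5.30), Ptx3 (4.86) and Ereg (4.80). Unstimulated means were 3.79 (Ptx3) and 4.21 (Fst) in NOD and 4.03 (Ereg) and 4.13 (Cyp1b1) in NOD.Idd3, near the 25th percentiles of the arrays (3.84 to 4.05). The sizes of such rises are limited by background, so their order, here and within each strain, is not established. Il1f6 encodes an IL-1 family cytokine and Ptx3 a soluble pattern recognition molecule. Serpinb2 rose by 4.73 ± 0.33, Tnfsf9 by 4.14 ± 0.16 and Inhba by 3.92 ± 0.27. Nos2, the inducible nitric oxide synthase gene, rose by 2.83 ± 0.57 and differed between replicate numbers, with 1.55 in replicate 1 and 4.12 in replicate 2. Il2ra, the alpha chain of the IL-2 receptor, rose by 2.69 ± 0.38.

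The largest falls were Cep19 (-3.26 ± 0.40), Rnase6 (-3.10 ± 0.33), Mtus1 (-2.96), Gm19696 (-2.92), Slc9a3r2 (-2.90), Tmem71 (-2.87), Susd3 (-2.81) and Zfand4 (-2.80). The chemokine receptor genes Cx3cr1 and Cxcr2 fell by 2.66 ± 0.35 and 1.79 ± 0.44. Dusp6, an ERK phosphatase gene, fell by 2.45 ± 0.49 while Dusp4 and Dusp2 rose by 2.47 ± 0.23 and 2.33 ± 0.19. Among the Toll-like receptor genes, Tlr5 fell by 1.88 ± 0.26 and Tlr8 by 1.63 ± 0.29, and Tlr2 changed by 0.41 ± 0.14 (adjusted p = 0.115). Tlr8 had a mean of 3.82 in PGN-treated NOD cells, near background. Tlr2 stood at 13.17 in unstimulated and 13.54 in PGN-treated NOD cells, where a rise could be compressed.

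The inflammatory cytokine list shifted upward by a median of 1.39 (camera adjusted p = 4.10e-12, and adjusted p = 0.226 with an estimated correlation). Of its 21 measured members 14 rose, 1 fell and 6 did not pass. Adjusted over the list alone, 16 rose and 1 fell. In the NF-kB list 12 of 22 members rose and none fell (median 0.67, adjusted p = 1.60e-10, and 0.40 with an estimated correlation), with Rel at 1.82 ± 0.14, Nfkbib at 1.57 ± 0.15 and Tnfaip3 at 1.30 ± 0.20. Adjusted over the list alone, 17 rose. Of 34 immediate early and MAPK feedback genes 12 rose and 3 fell (median 0.51, adjusted p = 8.41e-05, and 0.541 with an estimated correlation), or 15 and 3 adjusted over the list alone. Of 27 regulatory and tolerance-associated genes 10 rose and 1 fell (median 0.62, adjusted p = 8.41e-05, and 0.226 with an estimated correlation), or 15 and 2 adjusted over the list alone. Besides Il10 and Nos2, this list held Ptges at 2.66 ± 0.31 and Cish at 2.66 ± 0.38. The IL-2 family list, which also holds receptors and JAK-STAT genes, had 6 rises among 21 genes (median 0.39, adjusted p = 0.00147, and 0.226 with an estimated correlation), or 8 adjusted over the list alone, with Il4ra at 1.66 ± 0.19 and Stat5a at 1.16 ± 0.17.

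**Figure D2:**
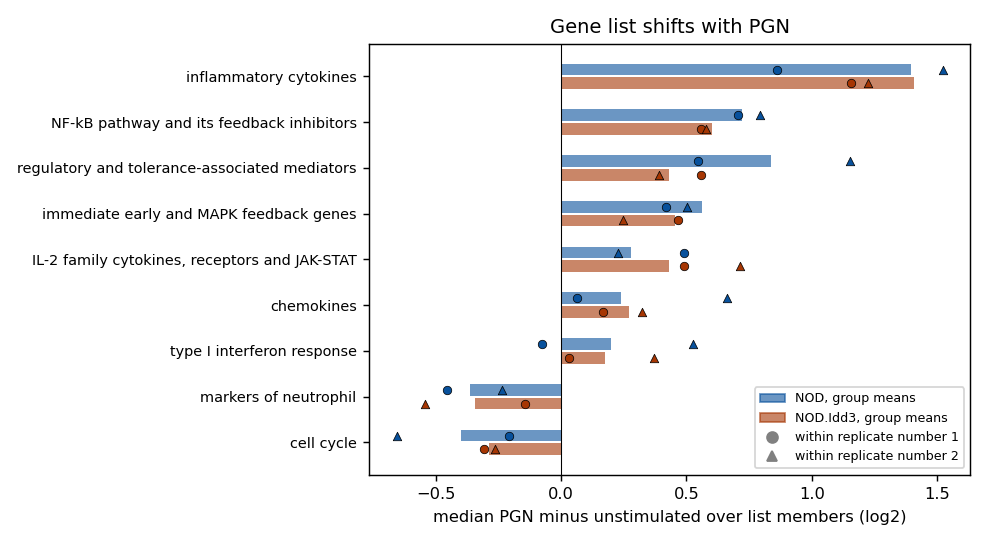
Median log2 change with PGN over the measured members of 9 gene lists, for NOD and NOD.Idd3. Bars give the change between means of 2 arrays and points the change within each replicate number. The inflammatory cytokine bars stand at 1.39 and 1.41.

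Downward shifts were called for neutrophil markers and cell cycle genes. Of 12 neutrophil markers 3 fell (median -0.32, adjusted p = 0.00514, and 0.509 with an estimated correlation), or 4 adjusted over the list alone. Without genes under the 40th percentile of mean value the list was not called (adjusted p = 0.0805). Mmp9 fell by 1.74 ± 0.19 and Mmp8 by 1.16 ± 0.17, while the granule genes S100a8 and S100a9, chosen after their values were seen, changed by -0.08 ± 0.15 and -0.10 ± 0.22. None of 27 cell cycle genes passed (median -0.38, adjusted p = 0.0145, and 0.809 with an estimated correlation). That list was not called in 5 further alternatives, among them without replicate 2 of unstimulated NOD (0.373) and without replicate 1 of PGN-treated NOD (0.18).

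The remaining lists were not called for the averaged PGN effect. Among chemokines 5 of 24 rose (median 0.22), led by Ccl4 (2.77 ± 0.34) and Cxcl1 (2.66 ± 0.60). Among peptidoglycan and Toll-like receptor sensing genes 4 rose and 5 fell (0.14), with Nlrp3 at 1.69 ± 0.34 and Irak2 at 1.49 ± 0.18. Antigen presentation genes had 3 rises (-0.04), including Cd40 at 1.10 ± 0.17 and Ciita at 1.42 ± 0.35. No type I interferon response gene passed (0.27), and Irf1 had the smallest p at 0.46 ± 0.15. Macrophage surface and scavenger receptors had 2 rises and 3 falls (-0.08), with Fcgr2b at 1.61 ± 0.26 and Clec10a at -1.94 ± 0.20. Glycolysis and hypoxia genes had 3 rises (0.30), with Pfkfb3 at 2.22 ± 0.14. Medians were -0.18 for oxidative phosphorylation with 0 passed, 0.01 for the NRF2 list with 3 rises, -0.05 for cholesterol and lipid efflux with 2 rises, 0.29 for heat shock with 1 rise and 1 fall, and -0.04 for the Idd3 list with 2 rises and 1 fall. With the replicate block 9 lists were called in place of 7, with the heat shock list (adjusted p = 0.00567, and 0.40 with an estimated correlation) and oxidative phosphorylation (0.0424, and 0.90 with an estimated correlation) added.

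Markers of other cell types moved as follows, none of them called as lists. T cell markers had 2 falls among 14 (median -0.24), with Cd3d at -1.48 ± 0.21, and platelet markers had 2 falls among 7 (-0.12), Ppbp at -2.67 ± 0.46 and Pf4 at -1.55 ± 0.25. Plasma cell markers had 3 rises among 6 (0.41), resident peritoneal macrophage markers 1 rise and 3 falls (-0.13), and macrophage markers 1 rise and 1 fall (-0.07). No marker passed for monocytes (-0.18), B cells (-0.07), mast cells and basophils (0.17) or erythroid cells (-0.25). Dendritic cell markers had 1 rise (0.06), NK cell markers 1 rise and 1 fall (0.00), regulatory T cell markers 1 of each (0.23), eosinophil markers 1 fall (-0.02), and stromal and endothelial markers 2 rises (0.22).

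In NOD cells alone, Cyp1b1 (7.36 ± 0.59, 2 arrays per group), Csf3 (7.28 ± 0.34), Il10 (6.54 ± 0.40), U90926 (6.30) and Il1f6 (5.97) had the largest rises with PGN. Il6 rose by 3.57 ± 0.54 (adjusted p = 0.0114), Il23a by 4.54 ± 0.74 and Il12a by 3.86 ± 0.75. Cep19 (-3.62 ± 0.56), Nlrp12 (-3.28 ± 0.39), Gm19696 (-3.12 ± 0.58) and Ppbp (-3.01 ± 0.64) had the largest falls. In all, 717 genes passed, 330 higher and 387 lower, and 1586 passed with the replicate block, including all 717. The count was 103 without replicate 2 of unstimulated NOD, and 442 and 77 without replicates 1 and 2 of PGN-treated NOD. The same 7 lists were called as over both strains, and the heat shock list as well (median 0.29, adjusted p = 0.0470, and 0.406 with an estimated correlation), in which Ddit4 rose by 2.79 ± 0.29. The inflammatory cytokine list had 10 rises (1.39), the NF-kB list 4 (0.72) and the regulatory list 6 (0.84). Over the 8 lists the adjusted p with an estimated correlation lay between 0.290 and 0.778. Cell cycle genes (-0.40, adjusted p = 0.0470, and 0.778 with an estimated correlation) had no member that passed, and the list was not called in 6 further alternatives. Without replicate 2 of unstimulated NOD its median turned to 0.061. The heat shock list was not called after a further quantile normalization (0.0641) or without replicate 2 of PGN-treated NOD (0.151), nor was the IL-2 family list without that array (0.0502). Neutrophil markers were not called without genes under the 40th percentile (0.132). With the replicate block 10 lists were called, with glycolysis and hypoxia genes (0.26, adjusted p = 0.0143, and 0.705 with an estimated correlation) and oxidative phosphorylation (-0.20, 0.0334, and 0.778) added. Without replicate 1 of unstimulated NOD 13 lists were called in place of 8.

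In NOD.Idd3 cells, Cyp1b1 (8.22 ± 0.59), Csf3 (6.85 ± 0.34), Il10 (6.50 ± 0.40), U90926 (5.82), Lipg (5.06 ± 0.74) and Saa1 (4.98 ± 0.37) had the largest rises. Nos2 rose by 3.96 ± 0.80, and Ido1, which encodes a tryptophan-degrading enzyme, by 2.46 ± 0.53. Il6 changed by 1.88 ± 0.54 and did not pass (adjusted p = 0.118, and 0.0145 with the replicate block). Rnase6 (-3.39 ± 0.47), Cx3cr1 (-3.30 ± 0.50) and Mtus1 (-3.04 ± 0.60) had the largest falls. Of 572 genes that passed, 344 were higher and 228 lower, and 1207 passed with the replicate block, including all 572. The count was 200 and 57 without replicates 1 and 2 of unstimulated NOD.Idd3, and 300 and 56 without replicates 1 and 2 of PGN-treated NOD.Idd3. The inflammatory cytokine list had 8 rises (median 1.41), the NF-kB list 4 (0.60), the regulatory list 6 (0.43) and the IL-2 family list 3 (0.43, adjusted p = 0.000148, and 0.222 with an estimated correlation). The lists called were the same 7 as over both strains, and their adjusted p with an estimated correlation lay between 0.222 and 0.922. Cell cycle genes (-0.29, adjusted p = 0.0487) had no member that passed, and the list was not called in 7 further alternatives. Immediate early genes were not called without replicate 1 of PGN-treated NOD.Idd3 (adjusted p of 0.287 in place of 0.000665). Neutrophil markers were not called without genes under the 40th percentile (0.0613) or without replicate 2 of unstimulated NOD.Idd3 (0.0595). The replicate block added the heat shock list (0.26, adjusted p = 0.0499, and 0.637 with an estimated correlation).

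The next question was whether the response to PGN differed between the strains. Across genes, which are not independent replicates, the PGN effects in NOD and NOD.Idd3 had a Pearson r of 0.80 and a Spearman rho of 0.62, and r was 0.79 within replicate 1 and 0.62 within replicate 2. Of the genes that passed in either strain, 884 of 888 had the same sign in both. There were 240 genes higher in both strains where 6.24 would be shared at random, 161 lower in both where 4.85 would be, and 0 opposite. The calls of both strains use the same estimate of spread for a gene, which can raise the overlap above such random values. Il10 rose alike, with a difference in response of -0.04 ± 0.57 (NOD.Idd3 minus NOD). The difference was -1.70 ± 0.76 for Il6, -0.51 ± 0.39 for Tnf, -0.85 ± 1.04 for Il23a, -0.19 ± 1.07 for Il12a and -1.31 ± 0.68 for Nlrp3, none of which passed.

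**Figure D3:**
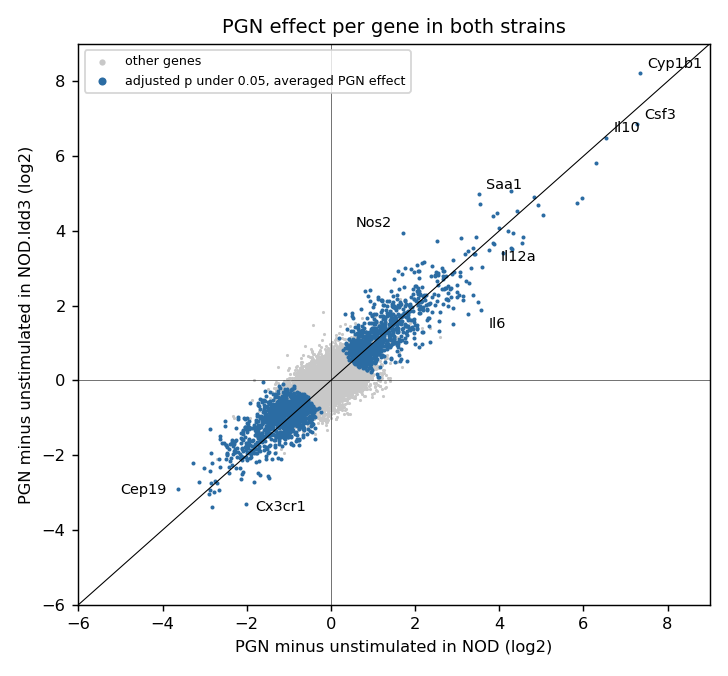
PGN effect of each of the 18193 genes (log2 change between means of 2 arrays) in NOD on the x axis and NOD.Idd3 on the y axis, with equal effects on the diagonal line. Blue marks the 2049 genes that passed for the averaged effect, over which r was 0.95. Choosing genes by the average of the same 2 effects raises r, which was 0.80 over all genes.

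For the difference in response limma called 0 genes, with 314 at an unadjusted p under 0.05 (1.73% of genes) and a smallest adjusted p of 1.00. With the replicate block 0 genes passed and 609 had an unadjusted p under 0.05. The smallest p-values belonged to Phxr4 (1.53 ± 0.31), 0610040J01Rik (2.02 ± 0.46), Poli (1.56 ± 0.37), Epb41l4b (1.57 ± 0.39) and Slc39a8 (1.43 ± 0.36). No list was called. The inflammatory cytokine list had a median difference of -0.23 (adjusted p = 0.152, and 0.0271 with the replicate block, and 0.907 with an estimated correlation), and none of its members passed. Without 1 array the number of lists called was 12 and 2 (replicates 1 and 2 of unstimulated NOD), 2 and 5 (replicates 1 and 2 of unstimulated NOD.Idd3) and 6 (replicate 1 of PGN-treated NOD.Idd3).

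The last comparisons asked how the strains differed at a given condition. RNA or labelling quality differed between the strains as well: the 3' minus 5' log2 difference of the Gapdh control probe sets was 0.88 to 1.16 on NOD and 0.72 to 0.80 on NOD.Idd3 arrays, without overlap. For Actb it was 0.43 to 0.58 and 0.22 to 0.46. Averaged over both conditions, the smallest p-values belonged to Mrc1, the mannose receptor gene (-1.56 ± 0.17, NOD.Idd3 minus NOD, 4 arrays per strain), the complement gene C1qb (-1.37 ± 0.15) and Gfra2 (-1.42 ± 0.16), each with an adjusted p of 0.0656 and 0.0226 with the replicate block. Tenm4 followed at -1.28 ± 0.15 and Gpd1 at -1.11 ± 0.14. These errors treat the 4 arrays of a strain as independent. Ms4a1, which encodes the B cell antigen CD20, stood at -1.71 ± 0.34 (adjusted p = 0.345, and 0.0226 with the block). Il2 differed by 0.08 ± 0.15 and Il21 by -0.07 ± 0.15, and both were dim, with Il2 at 3.49 in unstimulated NOD. Il10 differed by -0.17 ± 0.28, Il6 by 0.24 ± 0.38 and Tlr2 by -0.12 ± 0.14.

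Averaged over conditions limma called 0 genes, with 1175 at an unadjusted p under 0.05 (6.46% of genes). With the replicate block 27 passed, 2 higher and 25 lower in NOD.Idd3, and the following were chosen from these after their values were seen. The lower genes included C1qa (-1.42) and C1qc (-1.47), Fcna (-1.72), Igf1 (-1.58) and Cd5l (-1.53), and also Blk (-1.48), Tnfrsf13c (-1.46), Spib (-1.36), Cxcr5 (-1.34) and Cd79b (-1.31), which B cells express. The higher genes were Mid1 (1.20) and Htr7 (0.96).

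B cell markers were lower in NOD.Idd3 by a median of -1.13 (adjusted p = 1.78e-11, and 0.362 with an estimated correlation), and 10 of 12 were lower adjusted over the list alone. Macrophage markers were lower by -0.56 (adjusted p = 0.000126, and 0.362 with an estimated correlation), with 2 higher and 5 lower adjusted over the list alone. Platelet markers (-0.46, adjusted p = 0.000499, and 0.362 with an estimated correlation) and erythroid markers (-0.72, 0.0282, and 0.363) were called lower, as were dendritic cell markers (-0.15, 0.0281, and 0.362) and immediate early genes (-0.19, 0.00620, and 0.547). Cell cycle genes were higher by 0.37 (adjusted p = 1.70e-08, and 0.403 with an estimated correlation), with Ccna2 at 0.87 ± 0.32 and Aurkb at 0.67 ± 0.19. That shift came mostly from replicate 1, with a median of 0.706 within replicate 1 and 0.115 within replicate 2. Oxidative phosphorylation (0.17, adjusted p = 0.00150, and 0.671 with an estimated correlation) and monocyte markers (0.08, 0.0282, and 0.363) were also called higher. No member of these 9 lists passed over all genes. Further alternatives in which a list was not called numbered 7 for monocyte markers, 5 for erythroid markers, 4 for dendritic cell markers, and 3 each for immediate early genes and oxidative phosphorylation. The replicate block gave 13 lists, with the type I interferon response (0.10, adjusted p = 0.0295, and 0.786 with an estimated correlation), antigen presentation (-0.16, 0.0294, and 0.363), heat shock (-0.12, 0.0294, and 0.363) and resident peritoneal macrophage markers (-0.24, 0.0329, and 0.363) added. Without replicate 1 of unstimulated or of PGN-treated NOD.Idd3, 14 and 15 lists were called in place of 9.

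**Figure D4:**
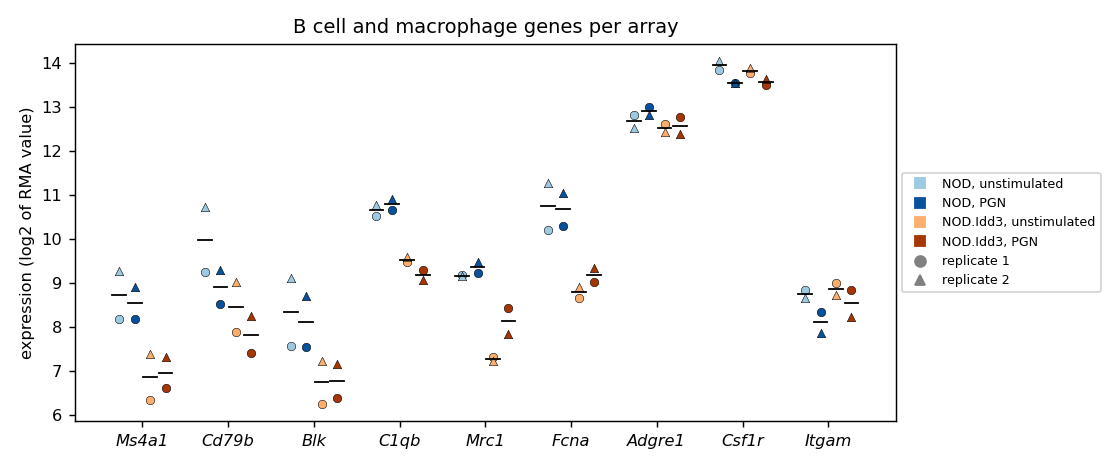
Expression of B cell genes (Ms4a1, Cd79b, Blk) and macrophage genes (log2 of the RMA value) on each of the 8 arrays, with colour for group, symbol for replicate number and a line for the mean of 2 arrays. C1qb had means of 10.66 and 10.80 in NOD and 9.54 and 9.19 in NOD.Idd3, unstimulated and with PGN.

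In unstimulated cells Mrc1 differed by -1.90 ± 0.24, Tenm4 by -1.58 ± 0.22, Tgm1 by -1.36 ± 0.19, Lhfp by -1.48 ± 0.24 and Gpd1 by -1.23 ± 0.20. Limma called 0 genes, with 611 at an unadjusted p under 0.05 and a smallest adjusted p of 0.358. B cell markers were lower by -1.34 (adjusted p = 5.04e-12, and 0.233 with an estimated correlation), with 9 of 12 lower adjusted over the list alone. Lower as well were erythroid (-0.92), macrophage (-0.56), eosinophil (-0.55, adjusted p = 0.0192, and 0.411 with an estimated correlation), platelet (-0.40) and dendritic cell markers (-0.24) and the IL-2 family list (-0.20, 0.0160, and 0.241). Cell cycle genes (0.33), monocyte markers (0.12) and oxidative phosphorylation (0.11) were higher. Without replicate 1 of unstimulated NOD the median turned to -0.091 for cell cycle genes and -0.114 for oxidative phosphorylation. Over the 11 lists called the adjusted p with an estimated correlation lay between 0.233 and 0.855, and no member passed over all genes. Further alternatives in which a list was not called numbered 6 for macrophage surface receptors, 4 each for the IL-2 family and oxidative phosphorylation, 3 each for eosinophil and dendritic cell markers, 2 for monocyte markers, and 1 each for erythroid markers and cell cycle genes. The replicate block gave 12, without macrophage surface receptors (-0.14, adjusted p = 0.0371, and 0.130 with the block) and with glycolysis and hypoxia genes (0.09, 0.0129 with the block, and 0.838 with an estimated correlation) and resident peritoneal macrophage markers (-0.19, 0.0398, and 0.269). Without replicate 2 of unstimulated NOD 5 were called. With PGN the 5 smallest p-values included those of C1qb (-1.61 ± 0.21), Gfra2 (-1.53 ± 0.22), Gsta2 (-1.31 ± 0.24) and C6 (-1.46 ± 0.28). Limma called 0 genes, with 984 at an unadjusted p under 0.05 and a smallest adjusted p of 0.783. B cell markers stood at -1.02 (adjusted p = 3.15e-06, and 0.679 with an estimated correlation). Macrophage markers (-0.56), platelet markers (-0.42), immediate early genes (-0.21) and the NF-kB list (-0.21, adjusted p = 0.0422) were lower too, and cell cycle genes (0.36) and oxidative phosphorylation (0.22) higher. The NF-kB list was not called in 6 further alternatives, oxidative phosphorylation in 3, immediate early genes and platelet markers in 2 each, and cell cycle genes in 1. Over the 7 lists called with PGN the adjusted p with an estimated correlation lay between 0.679 and 0.717. The replicate block gave 10, with inflammatory cytokines (-0.17, adjusted p = 0.0271, and 0.679 with an estimated correlation), the NRF2 list (-0.24, 0.0271, and 0.681) and heat shock (-0.12, 0.0264, and 0.679) added. In place of 7, 2 were called without replicate 1 of PGN-treated NOD, and 11 and 4 without replicates 1 and 2 of PGN-treated NOD.Idd3.

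The Idd3 list, of genes of the Idd3 interval and its flanks, held 26 measured genes, all on chromosome 3 in GRCm38.p6. Exosc9 was higher in NOD.Idd3 by 0.87 ± 0.21 (unadjusted p = 0.00243, adjusted p = 0.559), Mfsd8 by 0.85 ± 0.27, Bbs7 by 0.50 ± 0.18 and Plk4 by 0.54 ± 0.23, and Nudt6 differed by -0.66 ± 0.20, Spry1 by -0.38 ± 0.13 and Hspa4l by -0.45 ± 0.19. None passed. The list's median was -0.01 and it was not called, while fry's test of change in either direction gave an adjusted p of 0.0377 over the lists. With no gene called, the planned test of chromosomes had no genes to place. For the 27 genes of the replicate block the lowest adjusted p over chromosomes was 0.800, and for the 1175 genes at an unadjusted p under 0.05 chromosome 1 held 93 of its 1057 genes (one-sided Fisher exact test, adjusted p = 0.0339). Chromosome 3 held 68 of its 913 (adjusted p = 0.776 in the same test), and 1 of the 27. Both chromosome tests were chosen after seeing the data.

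**Figure D5:**
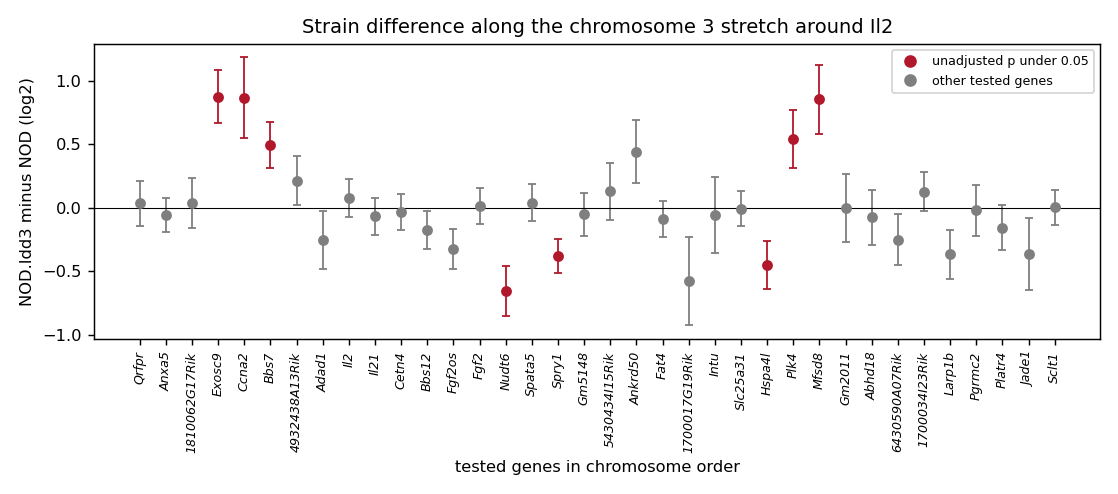
Strain difference averaged over conditions (log2, NOD.Idd3 minus NOD, bars give the SE over 8 arrays) for the 36 tested genes from Qrfpr to Sclt1 in chromosome order. Red marks the 8 genes with an unadjusted p under 0.05, such as Exosc9 at 0.87 and Nudt6 at -0.66.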

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

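The tests of other splits for the PGN effect were chosen after the result was seen, and those for the strain difference beforehand. The inflammatory cytokine list differed between strains in its response to PGN once the replicate block was in the fit, with a median of -0.23 (NOD.Idd3 minus NOD), an adjusted p of 0.0271 and none of 21 members passing. The median was -0.04 within replicate 1 and -0.52 within replicate 2, and without the block the adjusted p was 0.152, and 0.907 with an estimated correlation. The lower response in NOD.Idd3 therefore rests on the block and mostly on replicate 2.

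Probe sets that carry no gene symbol or several were left out of all comparisons, and 580 of these 10092 passed for the averaged PGN effect. Of the 580, 182 rose and 398 fell.

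Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes as the PGN split (2282 in a 2-group fit), the split itself, and the highest other split, by replicate number, gave 4. If the numbers pair the arrays, the 18 splits balanced in replicate numbers are the ones to compare. With the block the PGN split gave 2877 genes and the highest other, the strain split, 3, and 18 splits are too few for a share under 0.05. The strain split gave 0 genes (highest other 2282, the PGN split), so all 35 gave as many whatever the cause, and the count says nothing about chance. With the block the balanced splits other than these gave 0 genes.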

How the results depend on the processing

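The chromosome tests were chosen after seeing the data, and the other alternatives beforehand. No named gene that passed changed sign in any of them. The replicate block raised the genes called from 717 to 1586 (NOD), 572 to 1207 (NOD.Idd3), 2049 to 3082 (averaged PGN) and 0 to 27 (averaged strain difference), and lists for the difference in response from 0 to 1. It ended no gene call. Array weights gave 410 (NOD) and 994 (NOD.Idd3), and with 2 arrays per group they weight groups rather than arrays. The 4 arrays compared gave 416 (NOD). The RR1 term gave 235 (NOD.Idd3), 1 list for the difference in response and r = 0.745. With an estimated correlation 0 lists were called in the 6 contrasts that had any. The filter on dim genes gave 2 lists for the difference in response, 7 for the unstimulated strain difference, 12 with PGN, and r = 0.854. The mean of probe sets gave 1 list for the difference in response. Over the genes called r was 0.954, a value raised by choosing genes on the average of the same 2 effects. Within replicate 2 r was 0.615. Genes at an unadjusted p placed 1 chromosome past the threshold. The cause was not tested. Leaving out 1 array gave 77 to 876 genes (NOD), 56 to 624 (NOD.Idd3), 1111 to 2139 (averaged PGN), 0 to 0 in the 4 strain contrasts, and r from 0.690 to 0.805. Lists called ranged over 7 to 13 (NOD), 5 to 9 (NOD.Idd3), 6 to 10 (averaged PGN), 0 to 12 (difference in response), 5 to 12 (unstimulated), 2 to 11 (with PGN) and 6 to 15 (averaged strain difference). List medians reversed, over leave-one-out ranges of -0.873 to 0.061 for cell cycle with PGN in NOD (highest without replicate 2 of unstimulated NOD), and in the unstimulated strain difference -0.091 to 0.802 for cell cycle and -0.114 to 0.313 for oxidative phosphorylation (both lowest without replicate 1 of unstimulated NOD). Dim genes such as Il2 lie near background, where changes cannot be read.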

Other observations

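The tests of T and NK cell markers, general macrophage genes, granule genes and the chromosome 3 stretch were chosen after the results were seen, and those of other B-lineage and tissue macrophage genes beforehand. B cell markers were lower in NOD.Idd3 by a median of -1.13. T and NK cell markers had a median of -0.072 (SD 0.31, 12 genes), which argues against a smaller share of the main cell type in NOD raising all others alike. Erythroid (-0.72), platelet (-0.46) and dendritic cell markers (-0.15) were lower too, and eosinophil markers stood at -0.62, not called here but called lower in unstimulated cells (-0.55), so a change in several cell types stays open. More B cells among the NOD cells, despite the CD11b selection, was tested on 12 other B-lineage genes with a mean log2 value over 7. Their median was -0.086, with a 95% bootstrap interval of -0.26 to 0.04 from resampling the genes. Such an interval treats genes as independent and holds no error between arrays. It lay above the bound of -0.3 set beforehand, which by that rule argued against more B cells. This reading was changed after the value was seen, since 8 of the 12 genes had mean log2 values of 9.95 to 13.71, a baseline that could hide a small share, and the 7 genes outside this test that were dimmer had a median of -0.79 with 6 lower. The other 4, at 7.14 to 8.14, went both ways (Cd55 0.74, Cd180 0.06, Pou2af1 -0.35, Cnr2 -0.43). Whether other cells in these samples express the 12 genes was not tested, so they cannot argue against more B cells. More B cells in NOD may still be the source, but these values do not settle it. The Gapdh 3' minus 5' difference also separated the strains, and whether RNA or labelling quality contributes to any strain difference was not tested.

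C1qb, Mrc1, Cd163 and Fcna had a median strain difference of -1.64. For general macrophage and monocyte genes it was -0.049 (SD 0.27, 7 genes), but 4 of them had mean log2 values of 13.20 to 13.73, where a fall could be compressed. Of the others, Adgre1 stood at -0.24 ± 0.16, Fcgr1 at 0.54 ± 0.21 and Itgam, which encodes the CD11b selected for, at 0.28 ± 0.19. The first 2 argue against fewer macrophages and monocytes as a whole in NOD.Idd3 as the whole cause of falls this large, and a smaller loss stays open. The fixed macrophage list, which holds 4 of the 7 genes and C1qa, C1qb and C1qc, was called lower (-0.56). Tissue macrophage genes outside the fixed lists had a median of -0.42 (9 genes). Only 4 of them had a mean log2 value over 7, and these went both ways (Slc40a1 -0.70, Pltp -0.06, Spic -0.03, Maf 0.40). The others were dimmer, at 5.19 to 5.92, and stood between -0.86 and -0.27. The bootstrap interval for all 9 genes, again from resampling genes, was -0.70 to -0.03, on both sides of the bound of -0.3. Fewer cells of a tissue macrophage subset and lower expression per cell would both lower these genes, so the test cannot tell them apart. The interval spans the bound, so whether these genes were lower by more than that bound stays open too.

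Neutrophil markers were lower after PGN, with a median of -1.74 for Mmp8, Mmp9 and Cxcr2. The abundant granule genes S100a8, S100a9, Ngp, Camp, Ltf and Lcn2 had a median of -0.11 (SD 0.17), which by the rule of the test argued against fewer neutrophils. This reading was changed after the value was seen, since their mean log2 values of 13.67 to 14.75 lie near the highest of any gene, 15.17, where a fall could be compressed, and the 3 reference genes were picked after their falls were seen. Fewer neutrophils and lower expression per cell cannot be told apart.

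Strain differences may be more frequent in the stretch of chromosome 3 that holds the listed Idd3 and flanking genes than elsewhere. The stretch of 36 tested genes from Qrfpr to Sclt1 held 8 with an unadjusted p under 0.05, and 0.416% of 17321 equally long stretches, which overlap and include this one, held as many. In the Idd3 list, which includes flanking genes, 8 of 26 genes had such a p where 1.68 were expected (one-sided Fisher exact test, p = 0.000162). The nearest of the 8 to Il2 were Bbs7 and Nudt6. The genes between these, Il2 and Il21 included, had larger p-values. Of them, Adad1, Il2, Il21, Fgf2os and Fgf2 had mean log2 values of 3.06 to 3.57, near background, where a difference cannot be read. Whether the excess reaches Il2 itself therefore cannot be told. Both counts used the fit without the replicate block and were not repeated with it. Ccna2 and Plk4 act in the cell cycle. The cell cycle list, which holds Ccna2, was called higher in NOD.Idd3, mostly from replicate 1. A link to that shift and sequence variants under the probes were not tested and remain open.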
